A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

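Messenger RNA was measured on Affymetrix Yeast Genome S98 arrays, which carry probe sets of short oligonucleotides for the genes of baker's yeast, Saccharomyces cerevisiae. Per the series design, a strain deleted for CTH1 and CTH2 received the plasmid pRS416 without an insert, with CTH1 or with CTH2. These are called the vector, CTH1 and CTH2 groups, with 3 arrays in each group and 9 arrays in all. Every culture grew in medium lacking uracil with 100 µM bathophenanthroline disulfonate (BPS), a chelator that withholds iron, for about 6 hours at 30 °C, until the cells were dividing exponentially. Groups and replicate numbers were taken from the sample titles. The labels speak of independent transformation and triplicate growth but do not say whether each replicate was a separate transformant. The p-values therefore measure the spread between these cultures. RNA was extracted with glass beads and acidic phenol and labelled with biotin, per the labels' protocols.

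The deposited values are MAS5 probe-set intensity values on a linear scale, 1 per probe set and array, made by the authors with MAS5, per the submitters' processing notes; the version is not given in the sources used here. The mean signal without the lowest and highest 2% of probe sets lay between 500.4 and 500.6 on all 9 arrays, so each array had been scaled to 1 target before deposit. Detection calls and probe-level values were not used here. Microarray values carry no read depth, and the number of arrays limits the precision.

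The table held 9335 probe sets. Of these, 6504 had 1 gene in the platform annotation, 328 had several, 2443 had no gene listed and 60 were Affymetrix controls. All 6504 were matched to a gene of the RefSeq annotation of assembly R64 through the gene number, giving 5656 genes, of which 315 had several probe sets. Annotation was used for names and gene lengths only. The lengths were multiples of 3 for 97.1% of the protein-coding genes tested, and are called coding lengths. CTH2 is listed in the annotation under its standard name TIS11.

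Signals were floored at the 10th percentile of all named-gene values, a signal of 43.2, and log2-transformed. For a gene with several probe sets, the set with the highest mean was kept. Genes with a mean above the 25th percentile, a signal of 98.4, were tested, which left 4537 genes, 258 of them read by a probe set with a suffix that marks possible cross-hybridisation. Floored values made up 0.0882% of the tested values. The test was limma (version 3.58.1, R 4.3.3), with lmFit and eBayes with an intensity trend, on all 9 arrays in 1 model with no covariates, and Benjamini-Hochberg adjustment per comparison. A gene was called at an adjusted p under 0.05. Differences are given as log2 values with their standard error (SE) from that model, and each group's spread as a standard deviation (SD, n = 3).

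Also fixed before the data were examined were 31 gene lists. They cover the iron uptake regulon, the TCA cycle, the respiratory chain, ATP synthase, heme synthesis, iron-sulfur assembly, pyruvate dehydrogenase with lipoate, ergosterol synthesis with lipid desaturation, branched-chain amino acids, glutamate with lysine, arginine, sulfur with methionine, biotin, purines, glycolysis with fermentation, hexose transport, glycogen with trehalose, glyoxylate with gluconeogenesis, peroxisomal fatty acid oxidation, the zinc regulon, copper uptake and binding, the phosphate regulon, heat shock with general stress, oxidant defence, ribonucleotide reductase, mRNA decay, ribosome biogenesis, the mitochondrial ribosome, cytosolic ribosomal proteins, the mating pheromone response and the mitotic cell cycle. The cytosolic ribosomal protein list was defined by a symbol pattern that also takes in RPP1, a subunit of ribonuclease P. Lists were tested with camera of limma with a preset correlation of 0.01, adjusted over the 31 lists of a comparison, with an estimated correlation and fry as alternatives. Members were also counted as adjusted over the list alone.

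Genes to be named were fixed by a rule: CTH1 and CTH2 on every array, then, for each group against vector, up to 10 called genes each way by size of change whose arrays do not overlap the controls (5 each way for CTH2 against CTH1), up to 4 called members of each list, and, where nothing was called, the 5 genes with the smallest p each way. Members that passed only when adjusted over the list alone, and any beyond that rule, were chosen after their values were seen. The comparisons were CTH1 against vector, CTH2 against vector, CTH2 against CTH1, and the overlap of the comparisons against vector, set beside 100 simulations of unchanged groups because both use the same vector arrays.

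The procedure was tested on simulated data with the real means and spreads of the 4537 genes, in 20 draws with 200 changed genes. For CTH2 against vector, 6.4% of the genes changed by 0.5 on the log2 scale were recovered, 60.1% of those changed by 1, 95.4% at 1.5 and 99.2% at 2. For CTH1 against vector the shares were 6.6%, 57.7%, 95.5% and 99.6%. These shares hold where many genes change, since the adjustment is stricter when few do. The 20 draws gave 2722 calls for CTH1 against vector in all, where the real comparison gave 0. The shares therefore do not show which changes the real CTH1 comparison could miss, and there NCE101 did not pass at -1.85. False calls made up 5.16% of the simulated calls for CTH2 against vector and 4.7% for CTH1 against vector. In these draws genes varied independently, with the same spread on all arrays. The residual SD of the real arrays ran from 0.212 to 0.395. These shares are therefore not the rate of false calls in the real comparisons. A simulated shift of a list by 0.5 was called in 20 of 20 draws; genes in that simulation varied independently.

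Alternatives were other normalizations, floors and filters, no intensity trend, array weights, only the compared groups, the replicate number as a block, averaged probe sets, plain probe sets only, and each array left out in turn. For the lists, the alternatives fixed in advance were the estimated correlation, fry, quantile normalization and the replicate block, and for the overlap no floor, no filter, quantile normalization and the replicate block. The other alternatives for the lists and the overlap, and a correction for coding length, were added after the data were seen. A planned search for AU-rich elements downstream of the coding sequences needs genome sequence and was not run.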

Results

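The arrays compared iron-limited yeast that lacked both chromosomal genes for the mRNA-binding proteins Cth1 and Cth2 and carried either an empty plasmid, CTH1 or CTH2. Both proteins have tandem zinc fingers that bind AU-rich elements in mRNA, and the design asks what each protein alone changes when iron is scarce. There were 3 cultures with each plasmid, all grown with the iron chelator BPS, so no iron-replete sample enters any comparison. The authors' scaling gave median signals of 153 to 184 over the 9 arrays. Pairwise Pearson correlations over the 4537 tested genes ranged from 0.901 to 0.983. No pair of replicates was close to a duplicate, as the SD of the log2 difference between arrays of 1 group ran from 0.299 to 0.702.

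The targeted genes followed the labels on all 9 arrays. CTH1 had a signal of 231 to 592 in the 3 CTH1 arrays, 0.583 to 1.21 in the vector arrays and 1.54 to 14.3 in the CTH2 arrays. CTH2 had a signal of 3390 to 4500 in the 3 CTH2 arrays, 0.878 to 5.9 in the vector arrays and 1.81 to 10.2 in the CTH1 arrays. Set against the floor of 43.2, the group mean of the log2 signal was 7.87-fold higher for CTH1 and 89.6-fold higher for CTH2 in the group that carried it. These are lower bounds for the differences between group means, because the other arrays lay under the floor. CTH1 was too dim on average to enter the gene tests.

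The cells with CTH2 had lower mRNA levels of SDH2, ACO1, HEM15 and COX6, which encode mitochondrial enzymes or their subunits, than the vector cells. SDH2, the iron-sulfur subunit of succinate dehydrogenase, fell from a log2 signal of 10.72 ± 0.45 to 9.151 ± 0.36 (SD, n = 3), a difference of -1.57 (SE 0.26, limma adjusted p = 0.028). The iron-sulfur enzyme aconitase, ACO1 (-1.49, SE 0.25), the ferrochelatase that inserts iron into heme, HEM15 (-1.27, SE 0.21), and a subunit of cytochrome c oxidase, COX6 (-1.21, SE 0.2), fell too, each with a limma adjusted p of 0.028 and all 3 CTH2 arrays below the vector arrays. Outside the mitochondrion, FIT1, a cell wall mannoprotein that helps to retain siderophore-bound iron, differed by -1.42 (SE 0.26), and WTM1, which anchors the small subunit of ribonucleotide reductase in the nucleus, by -1.42 (SE 0.22). On the other side, HXT6 and HXT7, near-identical high-affinity glucose transporters, rose by 1.82 (SE 0.28) and 1.60 (SE 0.28).

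In all, limma called 13 genes between the CTH2 and vector arrays, 5 higher and 8 lower. One of the 5 is CTH2 itself, with a difference of 6.49 that is a lower bound because the other arrays sat at the floor. The remaining calls were the open reading frame YKR104W (-1.54, SE 0.24), the pheromone-regulated gene PRM4 (-0.96, SE 0.17), the cell wall mannoprotein HPF1 (1.38, SE 0.21) and RTC3 (1.17, SE 0.21), with limma adjusted p of 0.026 to 0.041. For each of the 12 genes other than CTH2, the 3 CTH2 arrays lay wholly outside the 3 vector arrays. These genes were called for their difference on the same arrays, so the separation is no separate support. Over all tested genes such separation held for 16.5%, where chance gives 10%. The HXT6 and HXT7 probe sets carry a suffix that marks shared sequence, so their values cannot be assigned to 1 gene. The calls were 5 higher and 14 lower with each array scaled to a common median, 6 and 6 with quantile normalization, 1 in all with a floor at the 25th percentile or with the replicate block, 2 with no filter on dim genes, 22 with only these groups in the fit, 25 after the coding-length correction and 72 with array weights. Leaving out vector replicate 2 or 3 or CTH2 replicate 1 or 2 left CTH2 as the only call, and 2 calls were left without CTH2 replicate 3. Without vector replicate 1 there were 6 calls, 5 of them among the 13 and NDI1 (-1.45) new, while 26 were made without CTH1 replicate 2. Over 22 alternatives the differences stayed about as large, from -1.56 to -1.28 for WTM1, from -1.71 to -1.21 for ACO1 and from 1.26 to 1.53 for HPF1.

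**Figure D1:**
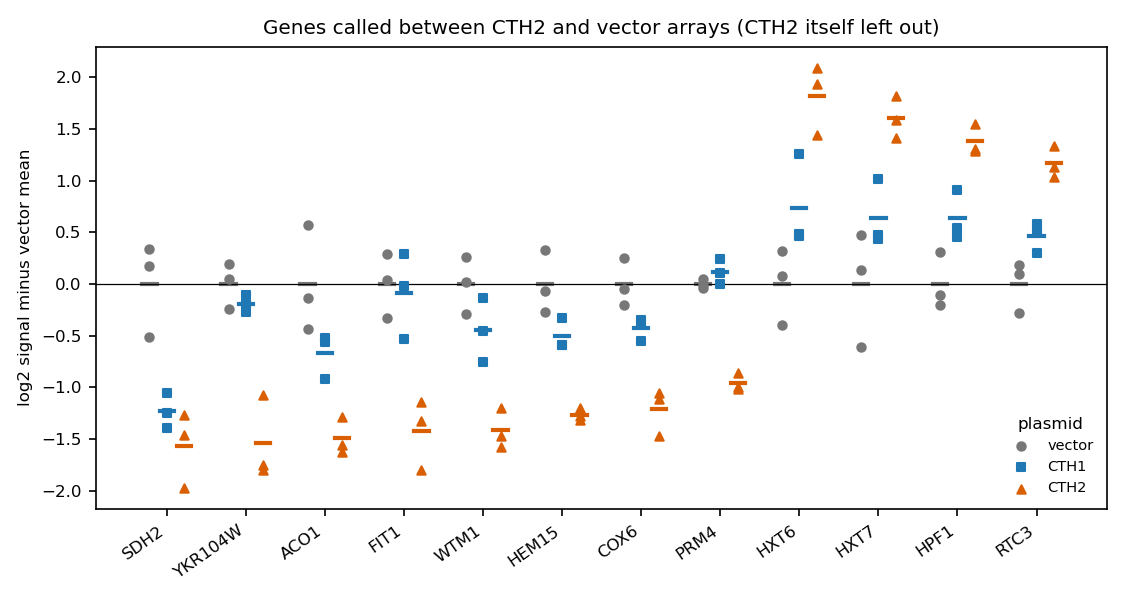
Log2 signal minus the vector mean (vertical axis) of the 12 genes other than CTH2 that were called between the CTH2 and vector arrays (horizontal axis). Symbols are single arrays, 3 for each plasmid, and short bars are group means. For each gene the CTH2 arrays lie outside the vector arrays, with mean differences from -1.57 for SDH2 to 1.82 for HXT6. The genes were called on these same arrays, so the separation is no separate support.

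Of the 31 lists, the respiratory chain had the most negative mean in the CTH2 arrays. Of 23 measured genes of the respiratory chain, 15 fell and 1 rose when adjusted over the list alone, and COX6 alone passed over all genes. Those that fell include CYT1 of complex bc1 (-0.99), COX4 of cytochrome c oxidase (-0.90), the internal NADH dehydrogenase NDI1 (-1.13) and the cytochrome c peroxidase CCP1 (-1.14). The gene that rose was COX5B (0.83), the oxidase subunit isoform used at low oxygen. The list mean was -0.64 (camera adjusted p = 2.3e-16, and adjusted p = 0.026 with an estimated correlation), with all 3 CTH2 arrays below all 3 vector arrays. Of 16 TCA cycle genes, 7 fell when adjusted over the list alone, among them SDH1 (-1.13), SDH3 (-0.98), SDH4 (-0.97) and KGD1 (-1.02), a subunit of the ketoglutarate dehydrogenase. ACO1 and SDH2 passed over all genes. The list mean was -0.57 (camera adjusted p = 8.5e-09, and adjusted p = 0.026 with an estimated correlation).

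Heme synthesis, ribonucleotide reductase and iron uptake were lower as well. HEM1 (-0.88), which starts the heme pathway, HEM4 (-0.59) and HEM15 fell when adjusted over the list alone, out of 9 heme genes with a list mean of -0.49 (camera adjusted p = 2.5e-05, and adjusted p = 0.03 with an estimated correlation). Of 8 genes for ribonucleotide reductase and its regulators, RNR2 (-0.67), RNR4 (-0.68) and WTM1 fell when adjusted over the list alone, and the mean was -0.51 (camera adjusted p = 1.2e-05, and adjusted p = 0.026 with an estimated correlation). In the iron uptake regulon, FIT1, the mitochondrial iron carrier MRS4 (-0.85) and the heme oxygenase HMX1 (-0.86) fell when adjusted over the list alone, and 20 of 22 members had values below 0. The mean was -0.33 (camera adjusted p = 2.6e-06, and adjusted p = 0.027 with an estimated correlation). The high-affinity iron oxidase FET3 (-0.17, SE 0.19) and its permease FTR1 (-0.26, SE 0.19) were among the 19 that did not pass. In each of these 3 lists the 3 CTH2 arrays lay below the 3 vector arrays.

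Storage carbohydrate genes were higher in the CTH2 arrays. The glycogen phosphorylase GPH1 (1.79, SE 0.36) and the glycogen synthase GSY1 (1.21, SE 0.25) rose when adjusted over the list alone, all 12 members had values above 0, and the list mean was 0.61 (camera adjusted p = 1.2e-05). That call was lost with an adjusted p = 0.12 with an estimated correlation. In lists that were not called, the hexokinase HXK1 (1.05), the stress genes HSP12 (0.91) and GRE3 (0.70) and the arginine synthesis gene ARG1 (0.70) rose when adjusted over the list alone. The low-affinity glucose transporter HXT1 (-0.60), the superoxide dismutase SOD2 (-0.73), the peroxiredoxin TSA1 (-0.71), the lipoate synthase LIP5 (-0.83), the glutamate synthase GLT1 (-0.89) and the peroxisomal thioesterase TES1 (-0.83) fell on the same terms.

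The other lists with lower values in the CTH2 arrays were called only with the preset correlation. In branched-chain amino acid synthesis (mean -0.40), the iron-sulfur enzymes LEU1 (-0.89) and ILV3 (-0.98) fell when adjusted over the list alone (camera adjusted p = 0.00018, and adjusted p = 0.17 with an estimated correlation). In the ergosterol and desaturation list (mean -0.14), the sphingolipid hydroxylase SCS7 (-1.07), ERG11 (-0.68) and ERG1 (-0.73) fell on those terms (camera adjusted p = 0.0091, and adjusted p = 0.14 with an estimated correlation). No member of the ATP synthase list passed (mean -0.28, camera adjusted p = 0.0015, and adjusted p = 0.14 with an estimated correlation). Nor did any of the mitochondrial ribosome (mean -0.07, camera adjusted p = 0.026, and adjusted p = 0.087 with an estimated correlation). The 81 cytosolic ribosomal proteins had a mean of -0.10 (camera adjusted p = 0.0019, and adjusted p = 0.66 with an estimated correlation), which became 0.009 under quantile normalization. Without CTH2 replicate 2 the ergosterol (-0.10, camera adjusted p = 0.087) and cytosolic ribosomal protein lists (-0.02, camera adjusted p = 0.48) were no longer called. The second of these was also lost without vector replicate 3 (-0.04, camera adjusted p = 0.19). The mitochondrial ribosome call ended without CTH2 replicate 3, where the mean shrank to -0.04 (camera adjusted p = 0.098). It also ended with means no smaller than with all arrays, without vector replicate 1 (-0.08, camera adjusted p = 0.071) or 3 (-0.08, 0.06) and after the coding-length correction (-0.11, 0.054).

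The 20 lists not called between CTH2 and vector had camera adjusted p of 0.074 to 0.99. Some passed with single arrays left out: iron-sulfur assembly without CTH2 replicate 1 (-0.18) or vector replicate 2 (-0.14), the mitotic cell cycle without CTH2 replicate 3 (0.29) or vector replicate 3 (0.25), purine synthesis without vector replicate 2 (0.37) and ribosome biogenesis without CTH2 replicate 1 (-0.09). With all arrays, the mitotic cell cycle had a mean of 0.23, hexose transport 0.37, purine synthesis 0.18, arginine synthesis 0.18, oxidant defence 0.15, copper uptake and binding 0.14 (called by fry, which tests whether the genes move 1 way, at an adjusted p of 0.038, with 7 of 8 members above 0), sulfur and methionine 0.12, heat shock and general stress 0.12, glycolysis and fermentation 0.09, the phosphate regulon 0.09 and mRNA decay 0.06. Biotin had a mean of -0.17 and pyruvate dehydrogenase with lipoate -0.08. The signs of mean, median and test did not all match for iron-sulfur assembly (mean -0.13, median 0.01), glutamate with lysine (-0.01, 0.10), glyoxylate with gluconeogenesis (0.04, -0.03), peroxisomal fatty acid oxidation (0, 0.04), the zinc regulon (0.03, 0.05, tested lower), ribosome biogenesis (0.01, -0.01) and the mating response (-0.04, 0).

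**Figure D2:**
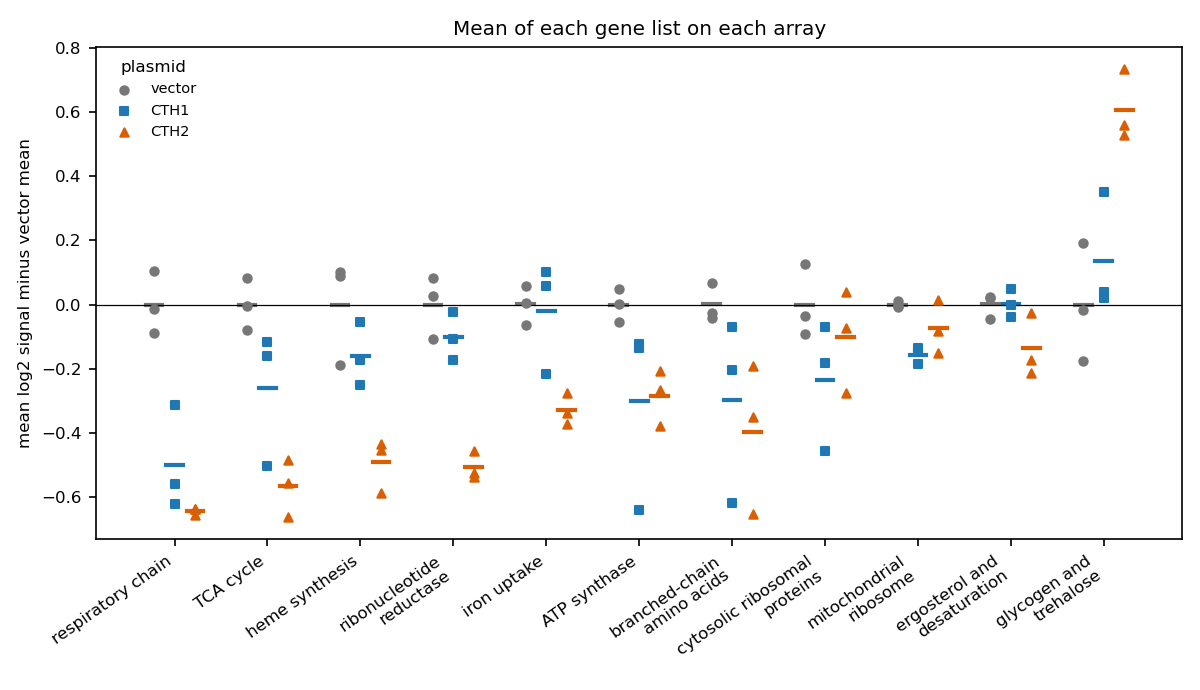
Mean log2 signal of each gene list minus its vector mean (vertical axis) for the 11 lists called between the CTH2 and vector arrays (horizontal axis). Symbols are single arrays, 3 for each plasmid, and short bars are group means; for the respiratory chain the group means are -0.50 with CTH1 and -0.64 with CTH2, and for iron uptake -0.02 and -0.33, while the cytosolic ribosomal protein mean with CTH2 changes sign under quantile normalization.

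Ribosomal RNA control probe sets differed along with these groups. The signal of a 25S rRNA probe set was 665 ± 324 in the CTH2 arrays and 3820 ± 721 in the vector arrays (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). It was 3310 ± 2950 in the CTH1 arrays. An 18S rRNA probe set had 271 ± 27.4 with CTH2, 723 ± 270 with vector and 1510 ± 918 with CTH1, so the CTH2 arrays lay below all arrays of both other groups (two-sided exact permutation p = 0.1 against each). The 3′ to 5′ signal ratio of ACT1, a measure of RNA integrity, was 1.33 ± 0.11 with CTH2, 1.16 ± 0.221 with CTH1 and 1.35 ± 0.256 with vector (SD, n = 3). That of SPT15 was 2.35 ± 0.689 with CTH2, 3.22 ± 0.215 with CTH1 and 2.53 ± 1.92 with vector, where it ran from 1.04 to 4.7, and the CTH2 arrays lay below the CTH1 arrays (two-sided exact permutation p = 0.1, the smallest possible).

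With CTH1, respiratory genes had lower values than with the empty plasmid, but no single gene passed over all genes. The respiratory chain list had a mean of -0.50, with 21 of 23 members below 0 and all 3 CTH1 arrays below the 3 vector arrays (camera adjusted p = 3.6e-12, and adjusted p = 0.079 with an estimated correlation). When adjusted over the list alone, QCR8 (-1.18) and QCR7 (-0.75) of complex bc1, the cytochrome c gene CYC1 (-0.93), COX9 (-1.13) and CCP1 (-1.44) fell. A dimmer probe set for QCR8 had 0.03, so its value rests on 1 of 2 probe sets. In the TCA cycle, SDH1 (-1.16) and SDH2 (-1.23) fell on those terms, and the list mean was -0.26 (camera adjusted p = 0.0099, and adjusted p = 0.43 with an estimated correlation). The mitochondrial ribosome list averaged -0.16 with MRPL33 (-1.33) the only member to fall when adjusted over the list alone (camera adjusted p = 0.0021, and adjusted p = 0.079 with an estimated correlation).

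In branched-chain amino acid synthesis LEU4 (-0.94), ILV5 (-0.91) and ILV3 (-0.73) fell with CTH1 when adjusted over the list alone (mean -0.30, camera adjusted p = 0.0063, and adjusted p = 0.43 with an estimated correlation). ATP synthase (mean -0.30, camera adjusted p = 0.011) and cytosolic ribosomal proteins (mean -0.24, camera adjusted p = 4.3e-08) had no member that passed, and each had an adjusted p = 0.43 with an estimated correlation. The 25 other lists had camera adjusted p of 0.066 to 0.83. Among them, hexose transport had a mean of 0.32, with the glucose transporter HXT5 (0.92) rising when adjusted over the list alone. The iron uptake regulon had a mean of -0.02 (camera adjusted p = 0.71), heme synthesis -0.16 (camera adjusted p = 0.15) and ribonucleotide reductase -0.10 (camera adjusted p = 0.3). Mean, median and test did not all have 1 sign for iron-sulfur assembly, pyruvate dehydrogenase with lipoate, ergosterol, glutamate with lysine and the mating response, with means of -0.05 to 0.01.

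Over all genes limma called 0 in CTH1 against vector, and 1 without CTH1 replicate 1, where NCE101 passed (-2.37). An unadjusted p under 0.05 was reached by 313 genes, 175 higher and 138 lower, where chance gives 227, and the smallest adjusted p was 0.406. The genes nearest to passing on the lower side were MRPL33, QCR8, MIC10 (-0.97), SDH2 and the secretion factor NCE101 (-1.85). On the higher side they were HXT5, the methionine permease MUP3 (1.04), the exchange factor ROM1 (0.98), the lipase ROG1 (1.06) and MPO1 (0.82). Arrays of the groups did not overlap for 10.2% of genes, with 10% given by chance.

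Short mRNAs set 1 CTH1 array apart. The median deviation of the 297 genes with a coding length of at most 400 nucleotides, minus that of the 3003 genes above 900, was -0.679 in CTH1 replicate 3 and between -0.0745 and 0.212 on the other arrays. MRPL33, QCR8, MIC10 and NCE101 have coding lengths of 261 to 305 nucleotides. Without that array the CTH1 list mean was -0.44 for the respiratory chain (camera adjusted p = 4.3e-07) and -0.13 for ATP synthase (camera adjusted p = 0.31), and with coding length corrected -0.38 (camera adjusted p = 1.6e-06) and -0.13 (camera adjusted p = 0.41). Cytosolic ribosomal proteins had a mean of -0.13 without that array (camera adjusted p = 0.011), against -0.24 with it. The mitochondrial ribosome list was no longer called after the coding-length correction (-0.12, camera adjusted p = 0.062), while ribosome biogenesis was (-0.15, camera adjusted p = 0.025). Over 24 alternatives the adjusted p of the respiratory chain ran from 1.9e-14 to 0.079 and that of ATP synthase from 0.00079 to 0.43. Without CTH1 replicate 2 the TCA cycle (-0.14, camera adjusted p = 0.23) and branched-chain lists (-0.14, camera adjusted p = 0.17) were no longer called, and their means were smaller. Without vector replicate 1 the calls of the TCA cycle (-0.26, camera adjusted p = 0.063), branched-chain (-0.31, 0.056) and ATP synthase lists (-0.30, 0.1) ended with means about as large as with all arrays, which left 3 lists. Heme synthesis passed without vector replicate 3 (-0.25, camera adjusted p = 0.024). Hexose transport (0.40, camera adjusted p = 0.017), heat shock (0.27, 0.035) and ribosome biogenesis (-0.17, 0.011) passed without CTH1 replicate 3, and heat shock (0.30, 0.02) also without vector replicate 2.

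**Figure D3:**
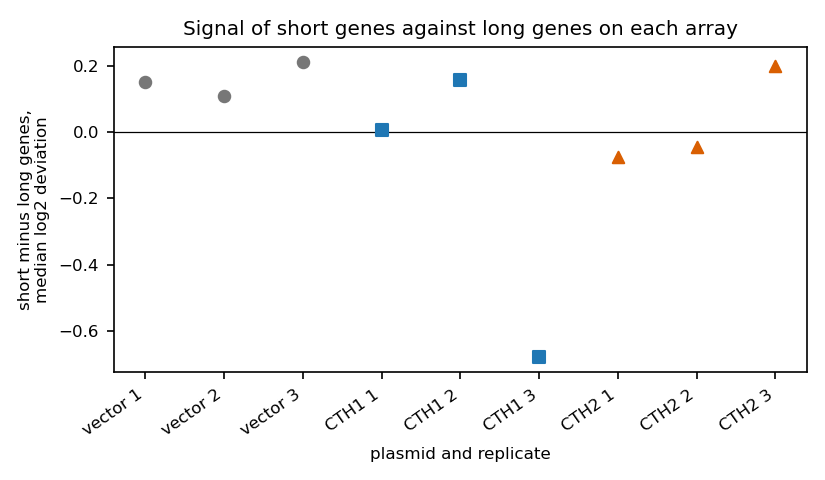
Median log2 deviation from the gene mean for short genes (coding length at most 400 nucleotides) minus that for long genes (above 900 nucleotides), on the vertical axis, for each of the 9 arrays on the horizontal axis. Each symbol is 1 array; CTH1 replicate 3 lies at -0.679, and the other 8 lie between -0.0745 and 0.212.

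Compared directly, the CTH2 cells had lower iron uptake, TCA cycle, heme and ribonucleotide reductase list means than the CTH1 cells, called with the preset correlation. None of these 4 calls held with an estimated correlation (adjusted p = 0.084, 0.13, 0.13 and 0.084 with an estimated correlation). With fry, ribonucleotide reductase was the 1 list called (fry adjusted p = 0.019). Another split of the same 6 arrays called 7 lists with the preset correlation, against 6 for the real groups. The 18S rRNA signal of the CTH2 arrays was below that of the CTH1 arrays as well (271 ± 27.4 and 1510 ± 918; SD, n = 3). The carried genes also had unlike signals, 231 to 592 for CTH1 and 3390 to 4500 for CTH2, each on its own probe set. A difference in dose was therefore not separated from a difference between the proteins. Limma called 1 gene, CTH2, and 339 genes had an unadjusted p under 0.05, with 13.4% of genes not overlapping. The iron uptake list differed by -0.31 (camera adjusted p = 1.9e-05, and adjusted p = 0.084 with an estimated correlation), with FIT1 (-1.34) and HMX1 (-0.81) lower when adjusted over the list alone. In the TCA list (-0.31; camera adjusted p = 0.00032, and adjusted p = 0.13 with an estimated correlation) KGD1 (-0.83), ACO1 (-0.82) and IDH2 (-0.63) were lower on those terms. Ribonucleotide reductase differed by -0.41 (camera adjusted p = 0.00032, and adjusted p = 0.084 with an estimated correlation), with WTM1 (-0.97), RNR4 (-0.62) and RNR1 (-0.57) lower.

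Heme synthesis differed by -0.33 between CTH2 and CTH1 cells (camera adjusted p = 0.0025, and adjusted p = 0.13 with an estimated correlation), with HEM15 (-0.76) lower when adjusted over the list alone. The ergosterol list differed by -0.14 with no member passing (camera adjusted p = 0.034, and adjusted p = 0.28 with an estimated correlation), and was not called without CTH1 replicate 3 (0.15) or CTH2 replicate 2 (0.27), or after the coding-length correction (0.069). Glycogen and trehalose genes were higher by 0.47 (camera adjusted p = 0.00032, and adjusted p = 0.28 with an estimated correlation), with GPH1 (1.64) and PGM2 (1.38) passing when adjusted over the list alone. The respiratory chain differed by -0.14 (camera adjusted p = 0.053), with COX4 (-0.70) and COX6 (-0.78) lower when adjusted over the list alone. It passed after the coding-length correction (-0.25, camera adjusted p = 0.00041) and without vector replicate 3 (0.047), CTH1 replicate 2 (0.042), CTH1 replicate 3 (0.01) or CTH2 replicate 3 (0.035); its range over 24 alternatives was 0.00041 to 0.68. The 25 lists not called had camera adjusted p of 0.053 to 0.94. With single arrays left out, 4 more of them passed: branched-chain amino acids without CTH1 replicate 2 (-0.26), cytosolic ribosomal proteins without CTH1 replicate 1 (0.22), CTH1 replicate 2 (0.16) or CTH2 replicate 2 (0.22), iron-sulfur assembly without CTH2 replicate 1 (-0.19) and ribosome biogenesis without CTH2 replicate 3 (0.22). Among them, HXT6 (1.09), HXT7 (0.96) and the biotin synthesis gene BIO4 (0.67) were higher and the biotin transporter VHT1 (-0.69), SOD2 (-0.73) and the pheromone-regulated PRM4 and PRM5 (-0.96) lower when adjusted over the list alone. Mean, median and test did not all have 1 sign for ATP synthase, glutamate with lysine, sulfur with methionine, biotin, glycolysis, hexose transport, heat shock, oxidant defence and the mating response, with means of -0.09 to 0.06. PRM4 (-1.07, SE 0.17) came nearest to passing over all genes, at a limma adjusted p of 0.093, and YKR104W (-1.35, SE 0.24) followed at 0.13. The count of genes was 0 with no floor and with a filter at the 50th percentile, where CTH2 itself is no longer tested, and 26 with array weights. Without CTH1 replicate 3 it was 3, adding GPH1 and PGM2, and without CTH2 replicate 3 it was 2, adding YKR104W.

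The signs of the differences from vector matched between CTH2 and CTH1 for 68.8% of the 4536 genes other than CTH2, where simulations of unchanged groups gave a mean of 66.7% and at most 68.3%. With CTH1 the differences from vector were -1.23 for SDH2, 0.74 for HXT6, -0.67 for ACO1, -0.50 for HEM15 and 0.12 for PRM4. Genes called with CTH2 were picked for their distance from the same vector arrays, so their signs with CTH1 are no separate test. None of the 12 genes called with CTH2 besides CTH2 itself was called in the direct comparison. CTH1 against vector called 0 genes, so no gene could be called in both comparisons. At an unadjusted p under 0.05, 40 genes were lower in both groups and 72 higher in both, with 0 in opposite directions. In 100 simulations of unchanged groups against the same vector arrays, the means were 23.9 and 23.2 and the highest counts 35 and 40, and independent lists would share 5.93 and 8.8. For opposite directions the simulated mean was 0.37 and the highest count 2, so the 0 observed is near what the shared vector arrays alone give. Across the 4536 genes, which are not independent replicates, the 2 sets of differences had a covariance of 0.0602, where the simulations gave a mean of 0.0374 and at most 0.0412, a difference from the mean of 0.0228. Pearson's r was 0.531 (simulated mean 0.498, highest 0.536) and Spearman's rho 0.519 (simulated mean 0.477, highest 0.504). The simulations include the sharing of the vector arrays but draw each gene independently, so deviations common to many genes on those arrays are not in them, and part of the excess may come from the shared controls. With the vector arrays divided between the comparisons, 1 for one and 2 for the other, the covariance averaged 0.0218 over the 6 divisions and ran from -0.00764 to 0.0462. Pearson's r then ran from -0.0486 to 0.318, Spearman's rho from -0.0245 to 0.316 and the share of equal signs from 52.1% to 62.6%. The values with vector replicate 1 alone in a comparison were the lowest.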

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

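The tests with matched random lists and with other splits of the arrays were set before their results were seen; those that left out an array, corrected for coding length or used the gluconeogenesis list were chosen after.

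Differences between the CTH2 and CTH1 groups passed camera with the preset correlation for 6 lists, and none of the 6 with an estimated correlation. The means were -0.31 for iron uptake, -0.31 for the TCA cycle, -0.33 for heme synthesis, -0.41 for ribonucleotide reductase, -0.14 for ergosterol and desaturation and 0.47 for glycogen and trehalose. CTH2 differed by 6.49, which the plasmids set by design. Among probe sets outside the gene tests, 1 with no gene listed was 2.04 above vector in the CTH2 arrays (SE 0.38, limma adjusted p = 0.03). Another, which the annotation gives to both CSS1 and HPF1, was 1.5 above vector (SE 0.22, limma adjusted p = 0.01).

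The 10 splits of 6 arrays are too few for a share under 0.05. For CTH1 against vector the real split called 0 genes, as did all 10 splits, and 6 lists, reached in 1 of the 10 splits, where the highest other split called 5; with an estimated correlation both were 0. For CTH2 against vector it called 13 genes against 0, 11 lists against 10, and 5 lists against 1 with an estimated correlation, each reached in 1 of the 10 splits. For CTH2 against CTH1 it called 1 gene against 40 and 6 lists against 7, each reached in 2 of the 10 splits, and 0 lists against 0 with an estimated correlation. The split with 40 genes sets CTH1 replicate 3 with CTH2 replicates 1 and 2. A structure of the arrays beyond the plasmids may underlie it, but 10 splits cannot tell this from chance. That split called 41 genes after the coding-length correction, so a trend of coding length is not its whole cause. Before the correction, the short-minus-long values of that split were at most -0.0447 in the arrays with CTH1 replicate 3. They were at least 0.00595 in the arrays set against them. No such values were computed after the correction.

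Respiratory chain mRNAs were lower with CTH1, and CTH1 replicate 3 had low signal for short mRNAs, and several of these genes, such as QCR8 and COX9, are short. Without that array the difference of list means was -0.44 (95% interval -0.67 to -0.20), and after the coding-length correction -0.38 (-0.60 to -0.17), against -0.50 with all arrays, so neither accounts for the whole difference. A trend of brightness or scaling is argued against by 10000 random lists matched on signal, among which the list stood at percentile 0. Their median was 0.02 and 95% of them lay from -0.11 to 0.14. Such lists draw genes independently, so here and below they do not address deviations shared by related genes. An effect of the CTH1 plasmid remains a candidate explanation, untested beyond the group comparison, and the call was lost with an estimated correlation.

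Iron uptake mRNAs were lower with CTH2, although all cultures received the same chelator dose. A trend of signal brightness or scaling is argued against by the list's place at percentile 0 among 10000 matched random lists, 95% of which had means from -0.16 to 0.10 against the list's -0.33. A single vector or CTH2 array as the whole cause is argued against too, since with each of the 6 left out in turn the 95% interval stayed below 0, its highest upper limit being -0.03. The lower ribosomal RNA signal of the CTH2 arrays moved with the group, and its part in the pattern was not tested. An effect of CTH2, direct or through the iron state of the cells, may underlie the pattern; these data hold no measurement of cellular iron.

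Glycogen and trehalose mRNAs were higher with CTH2, a call lost with an estimated correlation (camera adjusted p = 0.12). HXT6, HXT7 and HXK1, which yeast raises when glucose falls, were higher too. With CTH1, HXT6 (0.74), HXT7 (0.64) and HXK1 (0.59) also lay above the same vector arrays, though none was called. The glycogen and trehalose list mean with CTH1 was 0.14. With CTH2 that list stood at percentile 99.9 among 10000 matched random lists, which argues against brightness or scaling. Glucose used up in the CTH2 cultures would raise glyoxylate and gluconeogenesis genes too; their difference was 0.04, but its 95% interval of -0.72 to 0.80 includes the 0.61 of the glycogen list, so this explanation stays open. A smaller fall of glucose and an effect of CTH2 could each give the pattern, and they cannot be told apart here because glucose was not measured.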

How the results depend on the processing

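The coding-length correction, and most alternatives for the lists and the overlap, were chosen after seeing the data. CTH1 against vector kept 0 genes called except without CTH1 replicate 1, where NCE101 passed (-2.37, limma adjusted p = 0.05, under the threshold before rounding; 0.05 to 1 over its alternatives): leaving out arrays gave 0 to 1 genes called, 0 to 1 lower. Its lists called, 6 with camera, were 0 with an estimated correlation and 0 with fry, and 3 to 8 without single arrays, with 3 without vector replicate 1. For CTH2 against vector the 13 genes (5 higher, 8 lower) became 1 (1 and 0) with a floor at the 25th percentile, 2 (1 and 1) with no filter, 22 (9 and 13) with only the 2 groups, 72 (30 and 42) with array weights and 25 (9 and 16) after the coding-length correction. Median scaling gave 14 lower, and plain probe sets 3 higher because HXT6 and HXT7 leave the test. Without single arrays the range was 1 to 26 (1 to 9 higher, 0 to 17 lower), with the named arrays in the report. All 13 genes were kept with array weights, with only the 2 groups and after the coding-length correction, and 12 of 13 with median scaling, which moved the median of all genes from 0.066 to -0.056. Lists called were 11 with camera, 5 with an estimated correlation and 7 with fry, which adds glycogen with trehalose and copper uptake to those 5. The respiratory chain, TCA cycle, heme, ribonucleotide reductase and iron uptake lists passed under all 24 alternatives each. Apart from the estimated correlation and fry, these alternatives all used camera with the preset correlation. Leaving out arrays was not combined with an estimated correlation. Cytosolic ribosomal proteins reversed to 0.009 under quantile normalization. For CTH2 against CTH1 the 1 gene became 0 (0 higher) with no floor and with a filter at the 50th percentile, since CTH2 is then too dim to be tested. It became 2 (1 lower) with a floor at the 25th percentile, adding PRM4, 3 (2 lower) with no filter, adding PRM4 and CTH1, and 26 (14 higher, 12 lower) with array weights. Without single arrays it was 1 to 3 (1 to 3 higher, 0 to 1 lower). Lists called were 6 with camera, 0 with an estimated correlation and 1 with fry, ribonucleotide reductase. No gene was called in both comparisons against vector under any of the 21 alternatives run. CTH1 against vector called 0 genes except without CTH1 replicate 1, so elsewhere an overlap of 0 was fixed in advance. Apart from genes that leave the test, as said, the cause of these changes was not tested.

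Replicate numbers were not treated as pairs, since the labels do not say whether a number marks a shared day. Same-number deviations correlated over 0.1 in 2 of 9 pairs (-0.58 to 0.21), and 0 arrays correlated best with their own number. With 3 arrays in each group these values cannot exclude a pairing. With the replicate block CTH2 against vector called 1 gene (1 higher, 0 lower) in place of 13, and the counts for CTH1 against vector and CTH2 against CTH1 stayed at 0 and 1. The search for AU-rich elements and its 4 alternatives were not run. Signals near the floor of 43.2 limit what can be said of dim genes such as CTH1. Without the filter CTH1 was at least 2.98 higher with CTH1 than with vector, a lower bound because the vector arrays lay under the floor. Even so it was not called against vector (limma adjusted p = 0.095), although the plasmids set this difference by design.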

Other observations

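The list tested here and the genes named were chosen after their values had been seen. The hypothesis was that mRNAs of iron-containing proteins outside the fixed lists were lower with CTH2, for a list drawn up from general knowledge of which proteins bind iron or heme. Of 39 such proteins outside respiration, 18 were already in a fixed list; 19 of the other 21 were tested. Their mean difference between CTH2 and vector was -0.27 (95% interval -0.44 to -0.11), with 13 of 19 below 0. Lower when adjusted over the list alone were RLI1 (-1.08), an iron-sulfur protein of ribosome recycling, DPH2 (-0.93), which acts in diphthamide synthesis, and the heme-binding DAP1 (-0.84); none passed over all genes. With CTH1 the mean was -0.16 and the median 0.01, with 9 of 19 below 0 and 1 lower when adjusted over the list alone. The direct difference between CTH2 and CTH1 was -0.11, with 3 members lower and 2 higher when adjusted over the list alone. For all 35 tested iron proteins, those in fixed lists included, it was -0.18 with 26 below 0. Because the list was made after the values were seen, these values do not test the hypothesis, which stays open.

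Of the 40 genes lower in both groups at an unadjusted p under 0.05, the 4 with the largest differences with CTH2 that the text has not named were NFT1 (-1.28 with CTH1, -1.25 with CTH2), the pheromone gene MFA1 (-1.31, -1.20), the iron-sulfur assembly gene NFU1 (-0.85, -1.15) and HIS3 (-0.70, -1.14). Of the 72 higher in both, they were YNCD0009W (0.72, 1.32), PUG1 (0.91, 1.22), the mannosyltransferase gene MNN1 (0.69, 1.11) and TMA64 (0.74, 1). None of these passed over all genes. A probe set that the annotation gives to several genes was lower in the CTH2 than the vector arrays by -1.44 (SE 0.26, limma adjusted p = 0.03).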
